A study of Solanum tuberosum with 4 samples.

How the data were processed

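RNA was taken from tuber peel of 2 potato cultivars, each inoculated with Spongospora subterranea or given water, and 1 library per combination was sequenced. The labels mention 2 inoculated and 2 mock-inoculated plants and do not say how plants map to libraries. Groups were taken from the labelled cultivar and treatment of each sample, and the columns of the count table were matched to samples by their titles.

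The authors deposited 1 table of read counts per gene for the 4 libraries, together with gene lengths. Per the submitters' processing notes, Trim Galore, cutadapt, FastQC and HISAT2 (version 2.1) were used. The tool that counted reads, the strand setting, the treatment of reads mapping to several genes and the genome build are not given in the sources used here, so reads from overlapping, antisense or near-identical genes could not be told apart. The deposited counts are whole numbers with no normalization. A transcript at a low level in a cultivar could not be told apart from reads that failed to map. The table held 39028 rows, of which 12841 had no read in any library. One identifier stood on 3 rows with different lengths and counts. These rows were kept apart in all tests and left out of the naming of genes in the comparisons. Gene lengths were used only to look for length trends. Lengths were multiples of 3 in 60.3% of rows.

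The identifiers are those of the Potato Genome Sequencing Consortium. None of them matched the 32873 genes of the reference gene table at hand (SolTub_3.0), so gene names, products and positions were not used here. For that reason 28 lists of genes by product name, covering defence, hormone, cell wall, storage and stress genes, could not be applied, and neither could the planned list tests. The rule for named genes also asked for an informative product name. Without one it was applied on levels alone, and the first 2 genes in each direction are named in each cultivar comparison, of the 10 that the rule gives.

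Counts were scaled with edgeR's trimmed mean of M-values (TMM) over all rows, with factors of 0.987 (Innovator inoculated), 0.955 (Innovator control), 1.07 (Vanderplank inoculated) and 0.994 (Vanderplank control). Log2 CPM used a prior count of 2, which pulls ratios of low genes toward 0. Within a cultivar, genes with at least 1 CPM in either library were kept, and for comparisons over all 4 libraries genes with at least 1 CPM in at least 2. With 1 library per group these ratios have no test. For named genes a 95% exact binomial (Clopper-Pearson) interval on the ratio of the 2 counts is given. Intervals and floors cover counting error only, and PCR duplicates are not independent molecules. The floor is 3 counts, which is 0.095 to 0.104 CPM in these libraries. Depth was nearly equal, from 29219156 to 30215232 counts, and 1 read was worth 0.032 to 0.035 CPM. The 20 most abundant genes took 9.58% to 10.1% of the counts. No pair of libraries was alike enough to be repeat deposits of 1 library, since the chi-square statistic per degree of freedom between libraries was 88.7 or more. No batch is recorded in the labels.

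The tests over all libraries used edgeR 4.0.16 in R 4.3.3, with dispersions and quasi-likelihood fits of the additive model cultivar plus treatment, and a Benjamini-Hochberg adjusted p under 0.05. This model has 1 residual degree of freedom, the prior degrees of freedom were 4.21, and the biological coefficient of variation was 0.351. Nothing says that libraries of 1 treatment came from replicate units other than the cultivars. The error of a gene is therefore the difference of its inoculation response between cultivars, moderated toward the trend over all genes. With 4.21 prior against 1 residual degree of freedom, most of the weight lies on that trend. DESeq2 1.42.0 and limma-voom 3.58.1 were alternatives. Correlations of ratios, numbers of shared genes and the numbers expected of independent lists (the product of the list lengths over the genes compared) were computed over the same genes. Poisson draws of unchanged genes gave the size of counting error. The code was tested on simulated data, 5 sets of negative binomial counts for each of the 2 terms. Each set had 16545 genes, of which 200 were changed. Gene-wise negative binomial dispersions were scattered around the fitted trend with the prior degrees of freedom of the fit. The fit places that prior on the quasi-likelihood dispersion instead, and the mean simulated dispersion lay above the trend. A first version without that scatter recovered more of the changed genes and was replaced as too favourable. Over the 5 sets of a term, 19 unchanged genes were called for inoculation and 1 for cultivar. The changed genes called at 8-, 16- and 32-fold numbered 7, 34 and 88 for inoculation and 1, 4 and 12 for cultivar. False calls thus made up a larger share of the inoculation calls than the 0.05 threshold allows.

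The groups, tests, filters, alternatives and naming rule were set before the data were examined. Alternatives were other scalings, prior counts of 0.5 and 10, no filter or 5 CPM, thinning to equal totals, leaving out the 20 most abundant genes, other tools and leaving a factor out of the model. The cultivar ratios per treatment, the genes read in 1 cultivar, the split by mean CPM and the test of the crossed contrast were added after the data were seen. Counts of genes at least 4-fold above or below each of the other libraries were not planned either.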

Results

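Messenger RNA abundance was measured by RNA sequencing in the tuber peel of 2 potato (Solanum tuberosum) cultivars, Innovator and Vanderplank. The submitters describe Innovator as tolerant and Vanderplank as susceptible to Spongospora subterranea f. sp. subterranea, the soil-borne plasmodiophorid that causes powdery scab of tubers. Plants of each cultivar were inoculated 7 days after planting or given water, and were harvested 7 weeks after emergence. The design crosses cultivar with treatment and holds 4 libraries, 1 in each combination, so no group has a replicate. Libraries held 29772402 counts (Innovator inoculated), 30215232 (Innovator control), 29443715 (Vanderplank inoculated) and 29219156 (Vanderplank control). Between 22742 and 23472 gene rows had at least 1 read in a library, and 16545 reached 1 CPM (the standard library-size-scaled read count) in at least 2 libraries. Genes carry only Potato Genome Sequencing Consortium identifiers here, which are not paired with gene names, products or positions, so genes are described by identifier and no gene group or pathway could be followed.

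The 4 libraries were first compared with each other, to see how the cultivars and the treatments ordered them. Libraries of the same cultivar were the most alike. The log2 CPM of the 2 Innovator libraries correlated across genes at a Pearson r of 0.944 and that of the 2 Vanderplank libraries at 0.947, whereas pairs from different cultivars lay between 0.888 and 0.920. The 2 inoculated libraries were the least alike pair (r = 0.888) and the 2 control libraries the most alike pair across cultivars (r = 0.920). The differences among the 4 libraries divide into 3 independent contrasts with equal weights. These are inoculated against control, Innovator against Vanderplank, and the crossed contrast, which is the difference between the cultivars' inoculation ratios divided by 2. The cultivar contrast held 55.9% of the variance over genes, with an SD of 0.89 log2 units. The inoculation contrast and the crossed contrast held 22.1% each, with an SD of 0.56 for both. Poisson counting error alone gave an SD of 0.11 in each contrast. Among genes with a mean of at least 10 CPM the cultivar contrast held 51.5%, the crossed contrast 27.2% and the inoculation contrast 21.3%.

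**Figure D1:**
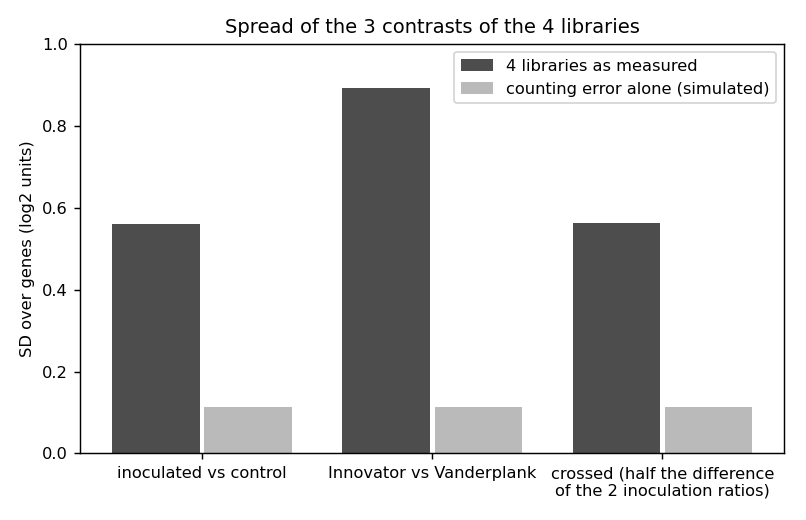
SD over 16545 genes, in log2 units, of the 3 contrasts of the 4 libraries (dark bars) and of the same contrasts in Poisson draws from unchanged genes (light bars, mean of 20 draws). The cultivar contrast (0.89) exceeds the inoculation contrast (0.56) and the crossed contrast (0.56).

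Inoculation of the tolerant cultivar Innovator was examined by setting its inoculated library against its control library. Of 17176 genes with at least 1 CPM in either, 1608 were at least 2-fold higher and 1518 at least 2-fold lower in the inoculated peel. At least 4-fold differences were found for 358 genes that were higher and 459 that were lower. Poisson draws with no difference between the libraries gave a mean of 7.6 higher and 7.35 lower genes at 2-fold and none at 4-fold, so these differences exceed counting error. Among 9712 genes with at least 10 CPM in the higher library, 502 were at least 2-fold higher and 455 at least 2-fold lower, together 9.85% of them. Of these better-covered genes, the highest ratio belonged to PGSC0003DMG400019415, with 612 reads after inoculation and 69 in the control (log2 ratio 3.09, 95% counting interval 2.76 to 3.50). PGSC0003DMG401028714 followed with 304 and 34 reads (log2 ratio 3.06, interval 2.62 to 3.69). The lowest ratios were those of PGSC0003DMG400018630, with 4 reads after inoculation and 499 in the control (log2 ratio -6.41, interval -8.87 to -5.62), and PGSC0003DMG400025842, with 5 and 314 reads (log2 ratio -5.53, interval -7.63 to -4.76). In Vanderplank, PGSC0003DMG400019415 had the opposite sign (102 reads after inoculation, 317 in the control, log2 ratio -1.73). The Vanderplank log2 ratios of PGSC0003DMG401028714 and PGSC0003DMG400025842 were 0.34 and -0.56, and PGSC0003DMG400018630 had 2 and 0 reads there, which is under the floor of 3 counts. With 1 library on each side, the comparison is between these 2 libraries and has no replicate check.

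The same comparison in the susceptible cultivar Vanderplank gave more genes that were lower after inoculation than higher. Of 16590 genes, 857 were at least 2-fold higher and 1644 at least 2-fold lower, and 158 and 480 passed 4-fold. Counting error alone gave a mean of 5.6 higher and 5.35 lower genes at 2-fold and none at 4-fold. The imbalance was larger among the 9754 genes with at least 10 CPM in the higher library, where 186 were higher and 738 lower. The median log2 ratio over genes was 0.01 after trimmed-mean scaling, and 0.11 with total library sizes. Of the genes passing 2-fold, 34.3% were higher with the trimmed-mean scaling and 43.9% with total library sizes. PGSC0003DMG400025774 had 464 reads after inoculation and 26 in the control (log2 ratio 3.94, 95% counting interval 3.47 to 4.67). PGSC0003DMG400015495 had 4075 and 256 reads (log2 ratio 3.87, interval 3.69 to 4.06). Both were also higher in inoculated Innovator, with log2 ratios of 2.34 and 2.15. Among genes with at least 10 CPM in the higher library, the lowest ratio was that of PGSC0003DMG400022340, with 19 reads after inoculation and 312 in the control (log2 ratio -4.01, interval -4.90 to -3.49). Next came PGSC0003DMG400004037, with 52 and 801 reads (log2 ratio -4.01, interval -4.49 to -3.66). In Innovator these 2 genes had log2 ratios of 1.17 and -0.85. This comparison, too, is between 2 libraries with no replicate check.

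**Figure D2:**
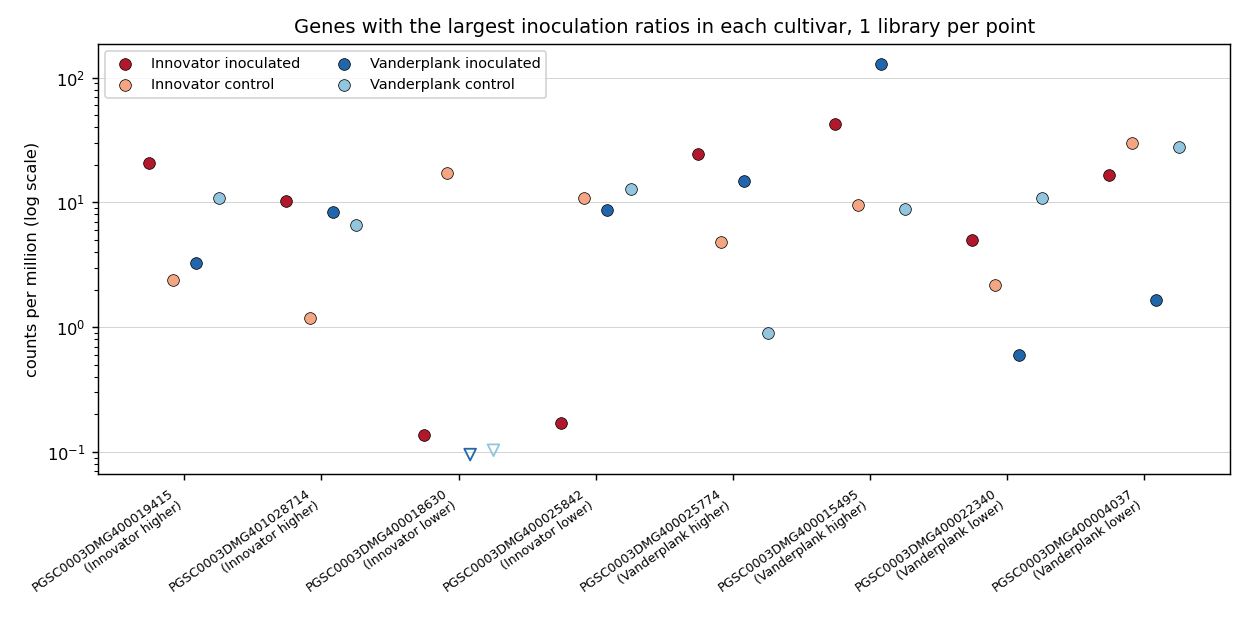
CPM (log axis) in each of the 4 libraries (1 filled circle each, open triangles for values under 3 counts, drawn at the CPM of 3 counts) for the 2 genes with the highest and the 2 with the lowest inoculation ratio in each cultivar, among genes with at least 10 CPM in the higher library. Both genes chosen as higher in Vanderplank are higher in the inoculated library of either cultivar, and PGSC0003DMG400019415 and PGSC0003DMG400022340 differ in opposite directions in the 2 cultivars.

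Whether the cultivars answered inoculation alike was assessed by setting their inoculation ratios side by side, which share no library. Across the 16545 genes Pearson's r between the ratios was -0.00016 (95% interval from resampling genes -0.021 to 0.020) and Spearman's rho was -0.056 (interval -0.070 to -0.040), and 46.5% of genes had the same sign in both cultivars. These correlations are across genes, which are not independent replicates. The absence of a Pearson correlation over all genes follows by arithmetic from the nearly equal SDs of the inoculation and crossed contrasts. It is no separate result. Among the 9222 genes with a mean of at least 10 CPM, r was -0.122 and rho -0.158, and 44.0% had the same sign. For the 7323 genes with a mean under 10 CPM, r was 0.059. At the 2-fold level, 161 genes were higher in both cultivars, against 57.5 for independent lists of the same lengths, and 216 were lower in both, against 119. A further 252 genes were higher in inoculated Innovator and lower in inoculated Vanderplank, against 122 for independent lists, and 83 were lower in Innovator and higher in Vanderplank, against 56.0. Every one of the 4 combinations thus exceeded the number for independent lists. That number takes every gene as equally likely to pass 2-fold, whereas variable or poorly covered genes can enter both lists in any combination. An excess by itself is therefore no sign of a shared response. At the 4-fold level, 16 genes were higher in both cultivars (1.40 for independent lists) and 20 lower in both (7.99), while 16 were higher in Innovator and lower in Vanderplank (5.45) and 3 the reverse (2.05). A model with the interaction leaves no residual degree of freedom among 4 libraries, so the difference between cultivars was tested only as the crossed contrast, with inoculation as the error.

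**Figure D3:**
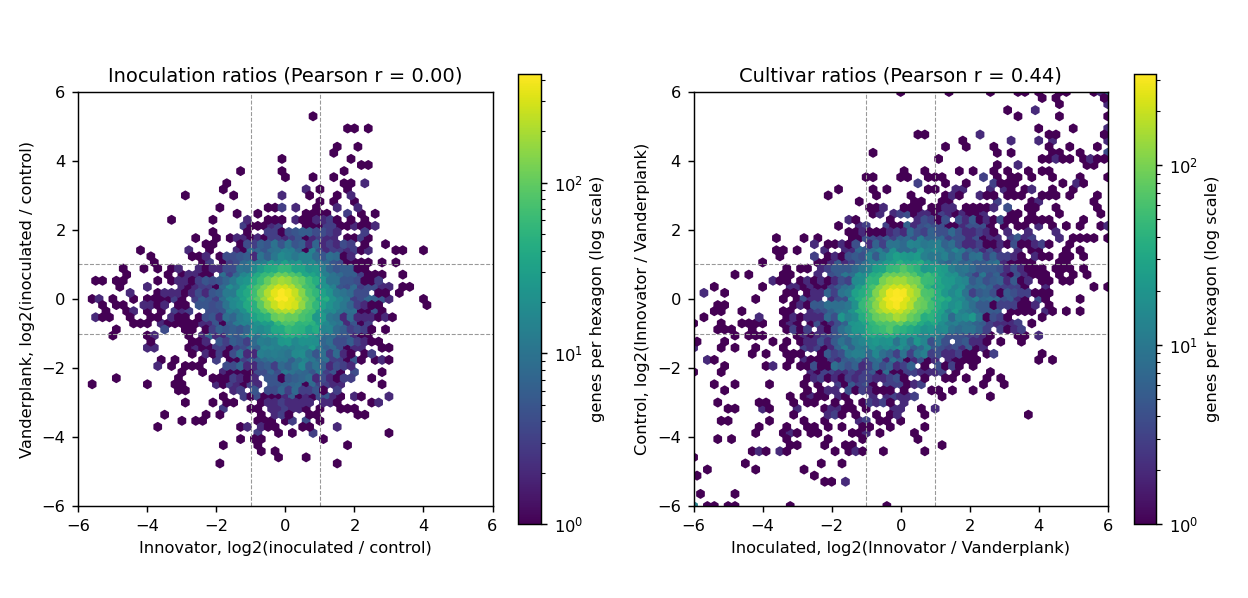
Log2 ratios of 16545 genes as density plots, with values beyond 6 drawn at the edge, dashed lines at 2-fold, and colour giving the number of genes in a hexagon on a log scale. The left panel sets the inoculation ratio in Vanderplank against that in Innovator (r = -0.00016), and the right panel sets the cultivar ratio in the control libraries against that in the inoculated libraries (r = 0.440).

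A test over both cultivars used an additive model with cultivar and treatment, in which any departure from the same response in both cultivars counts as error on 1 residual degree of freedom. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 16545 genes, 0 genes changed with inoculation, and the smallest edgeR adjusted p was 1.00. At an unadjusted p under 0.05 there were 612 genes (3.70%), below the 827 that chance alone would give. The crossed contrast, tested in the same way with inoculation as the error, gave 971 genes at that level and 0 after adjustment (smallest edgeR adjusted p = 0.804). DESeq2 with the same model called 20 genes, 8 higher and 12 lower after inoculation. The model counts disagreement between cultivars as error, so these calls are selected for agreement, and the call with the smallest adjusted p had only 0 and 1 reads in Vanderplank. PGSC0003DMG400015495 (log2 fold change 3.03, SE 0.49, DESeq2 adjusted p = 6.62e-06) and PGSC0003DMG400025774 (3.17, SE 0.57, DESeq2 adjusted p = 0.000109) were among those higher, and both had an edgeR adjusted p of 1.00. The inoculation calls therefore rest on the choice of tool. On simulated counts with gene-wise error like that fitted here, the edgeR test recovered 0 of 250 genes changed 4-fold by inoculation, 2.8% of those changed 8-fold, 13.6% of those changed 16-fold and 35.2% of those changed 32-fold.

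The cultivars were compared in both treatments, to see which genes distinguish Innovator from Vanderplank whether or not the plants were inoculated. With a single tolerant and a single susceptible cultivar, differences tied to tolerance cannot be told apart from any other difference between them. Of 17124 genes in the inoculated libraries, 2622 were at least 2-fold higher in Innovator and 1672 in Vanderplank. In the control libraries the numbers were 1723 and 1484 of 17028. The 2 sets of ratios share no library, and they moved together (r = 0.440, Spearman rho = 0.238), with 619 genes at least 2-fold higher in Innovator in both treatments, against 193 for independent lists, and 497 higher in Vanderplank in both, against 129. Another 145 and 94 genes passed 2-fold in opposite directions in the 2 treatments. The sign was the same for 56.6% of genes. At a mean of at least 10 CPM it was the same for 54.5%, with a lower r of 0.313 and rho of 0.155. With edgeR's quasi-likelihood test in the additive model, 0 genes differed between cultivars after adjustment (smallest adjusted p = 0.081), while 1676 genes (10.1%) had an unadjusted p under 0.05. DESeq2 called 525 genes, 322 higher in Innovator and 203 higher in Vanderplank. On the simulated counts, edgeR recovered 4.8% of genes changed 32-fold between cultivars and 0 of 250 changed 4-fold. The simulation treated both terms alike, so the gap from the 35.2% recovered for inoculation at 32-fold shows how unsteady these figures are. It does not show that the cultivar test is weaker.

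A few genes were read in a single cultivar. The folds below are of mapped reads, and reads that failed to map in a cultivar would lower its counts too. Mapping was not compared between the cultivars. With at least 5 CPM in both libraries of one cultivar and no read in either library of the other, there were 2 genes for Innovator and 5 for Vanderplank, and at a minimum of 1 CPM there were 25 and 13. No gene met either condition for treatment, that is, present in both inoculated libraries and without a read in both controls, or the reverse. The most abundant gene of each cultivar at the 5 CPM minimum is named here, chosen after its values were seen. At the 1 CPM minimum PGSC0003DMG400046798 was more abundant, with 112 and 4729 reads in inoculated and control Innovator and none in Vanderplank. PGSC0003DMG400024786 had 466 and 286 reads in inoculated and control Innovator and none in Vanderplank. Taking 3 counts per library as the floor, it was at least 166-fold higher in Innovator among inoculated and at least 95.9-fold higher among control libraries (edgeR adjusted p = 0.100, DESeq2 adjusted p = 0.129). PGSC0003DMG400034296 had 891 and 766 reads in inoculated and control Vanderplank and none in Innovator, at least 277-fold and 254-fold higher in Vanderplank (edgeR adjusted p = 0.081, DESeq2 adjusted p = 0.073).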

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

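The length correction and the exchange of labels below were chosen after the result they bear on was seen. The 10 genes listed first had an inoculation ratio at least 2-fold up in one cultivar and at least 2-fold down in the other, with at least 10 CPM in the highest library. They were picked for the size of that difference among genes reaching that level, and some genes under it differed by more. The difference was not tested against replicates, and as the crossed contrast, with inoculation as the error, edgeR called 0 genes (smallest adjusted p = 0.804, 971 genes at an unadjusted p under 0.05). Within the limit on level the largest negative difference was that of PGSC0003DMG400010112, with a log2 ratio in Vanderplank minus that in Innovator of -5.80. It had 62 reads in inoculated and 6 in control Innovator, and 92 and 612 in Vanderplank. The next 4 in this direction had differences of -5.76, -5.56, -5.18 and -5.18. With a prior count of 0.5 the gene after it stood first, at -6.42 against -6.08, but that gene rests on 2 reads in inoculated Vanderplank, under the floor of 3 counts, and has -4.35 with a prior count of 10. In the other direction, within the same limit, PGSC0003DMG400018575, a gene model of 165 bases, had 5.53 (2 and 36 reads in Innovator, 323 and 61 in Vanderplank), and the next 4 had 5.06, 4.99, 3.50 and 3.42. Its value rests on 2 reads, under the floor of 3 counts, and its first place depends on the prior count, as a prior count of 10 gives 4.09 for it and 4.33 for the gene after it.

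The inoculation ratios of the cultivars also ran weakly against each other among genes with a mean of at least 10 CPM (r = -0.122). The cultivars' ratios share no library, so counting error is not expected to tie them together. The lowest r in 20 Poisson draws was -0.020, which follows from that design and is no separate evidence. A length trend as the whole cause is argued against by an r of -0.121 once each ratio's trend with gene length was removed. An exchange of the inoculated and control labels in Vanderplank reverses the sign of r by arithmetic, so r does not bear on it. Genes differing at least 4-fold the same way in both cultivars were counted instead, over all 16545 genes. Their excess over independent lists was 3.83 times as given and 2.53 times exchanged. The ratio of 0.661 had a 95% interval from resampling genes (0.356 to 1.098) that includes 1. Among genes with a mean of at least 10 CPM, where the pattern lay, more 2-fold genes went opposite ways than the same way. There 26 were higher and 37 lower in both cultivars, against 5.42 and 25.9 for independent lists. Another 96 were higher in Innovator and lower in Vanderplank and 9 the reverse, against 25.2 and 5.59. An exchange therefore cannot be told apart from opposite responses. The test took 3 forms, each set after values were seen, and the first, which counted genes at least 4-fold lower in both cultivars (20 as given, 3 exchanged) without regard to list lengths, had argued against an exchange. Opposite responses of a tolerant and a susceptible cultivar, and differences between single plants or peel samples, remain open and were not told apart.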

How the results depend on the processing

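The correlation of the cultivar ratios, the split by mean CPM, the length correction, the repeated identifier and edgeR with legacy=FALSE were chosen after seeing the data. The calls depended on the tool and, for cultivar, also on the filter and model settings. DESeq2 gave 20 inoculation and 525 cultivar genes where edgeR gave 0 and 0. Inoculation calls stayed at 0 under the other alternatives run. Cultivar calls were 142 without a filter, 5 with treatment left out of the model and 26 with legacy=FALSE, and 0 with limma-voom, DESeq2 size factors in edgeR, total library sizes or a minimum of 5 CPM. The smallest adjusted p of the cultivar term ranged from 1.74e-26 with DESeq2 to 0.133 with edgeR at 5 CPM. The cause was not tested. The planned legacy=TRUE is this version's default and changed nothing by construction. The filter set the number of genes past 2-fold. Without it, Innovator had 3493 higher and 3440 lower and Vanderplank 2045 and 3504. At 5 CPM these were 759, 699, 319 and 984. The numbers past 4-fold (358, 459, 158 and 480) became 800, 933, 432 and 872 without a filter and 122, 147, 36 and 264 at 5 CPM, and a prior count of 10 gave 176, 281 and 74 for the first 3. These follow from the genes kept and the shrinkage. At 5 CPM, 49 genes were higher and 78 lower in both cultivars, 141 higher in Innovator and lower in Vanderplank, and 20 the reverse. The last of these numbers, 83 at the reported settings, was 50 with a prior count of 10. The correlation of the inoculation ratios changed with level. Pearson r and Spearman rho were -0.084 and -0.124 at 5 CPM, -0.122 and -0.158 at a mean of at least 10 CPM and 0.059 and 0.025 under it, and r was -0.121 with the length trend removed at that mean. Cultivar ratios gave r = 0.475, 0.388 and 0.394 with a prior count of 0.5, a prior count of 10 and 5 CPM. The SDs of the inoculation, cultivar and crossed contrasts under the same 3 settings were 0.59, 0.98 and 0.59, then 0.49, 0.75 and 0.50, then 0.45, 0.73 and 0.49. For the 8 genes named by cultivar and the 2 largest opposite differences each way within the level limit, 72 values were computed under 6 alternatives. None changed sign, and 4 moved by more than 1 log2 unit, all with a prior count of 10. These were 2 of the opposite differences and the 2 lowest Innovator ratios. With that prior count PGSC0003DMG400018630 had -5.22 and PGSC0003DMG400025842 had -4.47, both outside their counting intervals. The genes read in a single cultivar were not among them. Leaving out a library leaves the additive model no residual degree of freedom, so it gives no calls. The additive model pairs the libraries by cultivar, and replicate numbers give no further pairs, as each group has 1 library. The gene list tests and their alternatives were not run, as no gene names were at hand. Depth was nearly equal and does not limit the comparisons of well-covered genes. The absence of replicates does.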

Other observations

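The counts of genes far below or above the other libraries were not among the planned results. The tests on depth and on abundant genes below were chosen after their results were seen. The test of scaling was added once the floor test had been run. More genes lay at least 4-fold below each of the other 3 libraries in the inoculated libraries (130 in Innovator, 215 in Vanderplank) than in the controls (53 and 41), a ratio of 3.67, although the inoculated pair is 1 of the 6 ways to choose 2 of the 4 libraries. Total counts of the inoculated libraries were 0.996 times those of the controls, which argues against depth, and the ratio was 2.82 with total library sizes in place of TMM, which argues against scaling as the whole cause. Among genes with at least 10 CPM in the other 3 libraries it was 11.4 (18 and 73 against 7 and 1), which argues against reads near the floor but rests on inoculated Vanderplank, since Innovator alone gives 2.57. The 20 most abundant genes took 0.981 times the share of reads in the inoculated that they took in the control libraries. They held only 9.58% to 10.1% of the counts in any library, too little to push other genes 4-fold down. The comparison of shares was therefore bound to go against crowding by these genes and adds no weight. A loss of transcripts from infected peel is a candidate explanation, and a difference in the tissue or RNA quality of single samples is another. Neither was tested. Without gene names no tissue markers could be followed, but gene lengths were at hand. Spearman's correlation of the inoculation ratio with gene length was -0.030 in Innovator and 0.119 in Vanderplank. This trend was not examined for the far-lower genes and does not decide between the explanations.

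Genes at least 4-fold above each of the other 3 libraries numbered 46 in inoculated Innovator, 27 in control Innovator, 3 in inoculated Vanderplank and 31 in control Vanderplank.

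The identifier PGSC0003DMG400002414 stands on 3 rows. One of them, of 726 bases, had 3756 reads in control Innovator, 148 in inoculated Innovator, and 26 and 14 in inoculated and control Vanderplank. Another, of 3716 bases, had between 2097 and 2759 reads in every library. The gene that the 726-base row belongs to was not identified.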
